A study of Rattus norvegicus with 11 samples.

How the data were processed

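RNA was sequenced from snap-frozen retroperitoneal white adipose tissue of 11 ovariectomized female rats, 1 library per rat, from 6 rats on degarelix only and 5 rats on degarelix plus FSH. Per the labels' protocols, the total RNA was made into mRNA-seq libraries with a strand-marking kit and sequenced as paired ends. The deposited values are whole-number counts per Ensembl gene with no normalization, 1 column per rat, as the file's values show. Per the submitters' processing notes, STAR, edgeR, DESeq2 and the rat genome build rn6 were used, with no roles or versions stated. The counting program, the annotation release and the strand setting of the counting are not given in the sources used here. Genes that overlap or lie antisense to one another, and genes with near-identical copies, can therefore share or lose counts, and their values are uncertain. The 13 mitochondrially encoded rows hold 0 counts in every library, so no mitochondrial share was computed. No genome positions are printed, because the gene table used here is of another assembly (GRCr8), which served only to match older symbols.

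Columns were assigned to rats by names that match the labels, and groups came from the labels. The table held 25275 genes. Pcmt1 was left out because 1 of its cells holds a letter in place of a count. Of the rest, 17034 genes had at least 1 count, and edgeR's filterByExpr kept 12846 for testing. Total counts per library lay between 13163021 and 23694602. A count of 0 therefore allows up to 0.127 to 0.228 CPM (3 counts of the library's total), and such limits cover counting error only. Libraries were compared in pairs by a chi-square test over genes, and the lowest chi-square per degree of freedom was 22.5, so none was treated as a repeat of another.

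The comparison was fitted with edgeR 4.0.16 in R 4.3.3 (TMM factors, robust quasi-likelihood F test, intercept and group, 9 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. All tests were read two-sided. Expression is given as CPM (counts relative to the TMM-scaled library total), with SD between rats, and log2 changes carry the standard error derived from the quasi-likelihood test. The biological coefficient of variation was 0.191. The median log2 change of all genes was 0.00812 with TMM, 0.00166 with DESeq2's size factors and 0.0196 with upper-quartile factors.

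Before the data were examined, 28 gene lists and 20 cell type marker lists were fixed. The gene lists cover lipid, sterol and carbohydrate metabolism, mitochondria, adipocyte function, hormone and stress responses, immunity, matrix, vessels, cell cycle, clock and ribosomes, and the marker lists cover the cell types of adipose tissue and of neighbouring organs. Of their symbols, 583 matched the file directly, 6 through a synonym, 18 were not matched and 4 stood on several rows and were left out. Lists with at least 5 members tested (27 and 12) entered limma 3.58.1's camera test on log2 CPM (prior count 2) with the preset correlation of 0.01, adjusted over all 39 lists together. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance and compares them with no other genes, were alternatives. Each list was also scored per rat (mean of centred log2 CPM), and group differences in scores, in summed marker CPM and in library measures were tested by exact permutation over all 462 splits, which can give no p below 0.00216.

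The rule for the genes named, also fixed before the data were examined, took the 12 genes of smallest p in each direction past the threshold with a true symbol, up to 4 members of each list past camera in the list's direction, the 3 largest changes per direction among genes past the threshold with a mean of at least 1 CPM, and 14 genes named in advance (Fshr, Ucp1, Lep, Adipoq, Pparg, Fasn, Srebf1, Lpl, Lipe, Pnpla2, Dgat2, Ppargc1a, Esr1 and Ccl2). Members singled out outside this rule, such as Acacb, Ptpn1, Cpt1a, Gata2, Rxra, Zbtb46 and single nerve markers, were chosen after their values were seen. Some genes that the rule takes are not reported here.

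The alternatives were 2 other scalings, no low-count filter, a filter of 1 CPM in 5 libraries, each library left out in turn, the replicate number as a block, DESeq2 1.42.0, limma-voom with and without sample quality weights, edgeR without robust estimation, a threshold of 0.10, an added 1.5-fold limit and 1 surrogate variable (sva 3.50.0). Thinning every library to the smallest total was added after seeing the data. The test was also run on 100 of the 462 splits of the libraries. The edgeR and camera steps were tested on simulated data of the same 12846 genes with 200 genes changed. The edgeR step recovered 9 of 50 genes at 1.3-fold, 29 at 1.5-fold, 43 at 2-fold and 45 at 3-fold, with 5 false calls among 131. Camera called 0 of 40 unchanged lists there, but the simulated genes varied independently of one another, unlike real ones.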

Results

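Retroperitoneal white adipose tissue was taken from 11 female Wistar rats whose ovaries had been removed, and RNA was sequenced from each rat separately. The rats were 10 weeks old at the start, ate a western diet for 6 weeks before surgery, and then received degarelix, an antagonist of the gonadotropin-releasing hormone receptor that lowers the pituitary's output of luteinizing hormone and follicle-stimulating hormone (FSH). Implanted pumps delivered vehicle to 6 rats (degarelix only) and FSH at 6 µg per kg per day to 5 rats (degarelix plus FSH). Food was limited for 12 days, then given freely for 7 days, and tissue was collected at 19 weeks of age after a 4 h fast. The comparison asks how FSH changes adipose gene expression where ovarian hormones are gone and the animals' own gonadotropins are suppressed. All differences are given as degarelix plus FSH relative to degarelix only.

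Total counts ranged from 16452117 to 23694602 in the degarelix only libraries (mean 19947536 ± 2898450, SD, n = 6). They ranged from 13163021 to 19837706 in the degarelix plus FSH libraries (mean 16370093 ± 2501006, SD, n = 5), a difference with p = 0.0649 in a two-sided exact permutation test over the 462 possible splits. The first principal component held 22.7% of the variance and differed between the groups (p = 0.00866, exact permutation test). FSH replicate 3 lay farthest out on it, at 44.18, where the other FSH libraries lay between 2.583 and 12.65; this library also had the lowest total count. No pair of libraries agreed within sampling noise.

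With FSH, 155 genes were higher and 137 lower past the threshold. In limma's camera test with the preset correlation, endothelial cell markers passed as higher (1 of 9 members past the threshold over all genes), and cholesterol synthesis (4 of 19) and fatty acid synthesis (1 of 16) passed as lower. None of the 3 lists passed with an estimated correlation (adjusted p = 0.736 for each), and 76 of 100 splits of the libraries gave at least as many lists as the real split. Gpihbp1 (ENSRNOG00000007475), which carries lipoprotein lipase to the capillary surface, rose from 297 ± 30.8 to 460 ± 22.2 CPM (counts scaled to the library's normalised total; SD, n = 6 and n = 5; log2 change 0.63 ± 0.08 SE, adjusted p = 0.00524). Cd300lg (ENSRNOG00000020837), a glycoprotein of capillary endothelium, rose from 84.1 ± 11.4 to 153 ± 17.3 CPM (log2 change 0.86 ± 0.11, adjusted p = 0.00509). The endothelial transcription factor Sox17 rose 1.54-fold and Smtn, a cytoskeletal protein of smooth muscle, rose by a log2 change of 0.68. Insig1 (ENSRNOG00000006859), the endoplasmic reticulum protein that holds back the sterol-sensing transcription factors SREBP, fell from 1706 ± 453 to 761 ± 139 CPM (log2 change -1.17 ± 0.19, adjusted p = 0.0159).

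With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 292 of 12846 genes passed an adjusted p of 0.05, 155 higher and 137 lower. The median log2 change was 0.47 among the higher genes and -0.47 among the lower ones, and 17 genes changed by over 2-fold (8 higher, 9 lower). At an unadjusted p under 0.05, 2904 genes passed. The groups did not overlap at 557 genes (4.34%, against 0.433% by chance), of which 239 were among the 292. The count depended on single libraries. Without degarelix only replicates 1 to 6 in turn it was 51, 125, 152, 532, 78 and 50. Without FSH replicates 1 to 5 in turn it was 47, 30, 92, 551 and 49, and 84 of the 92 genes called without FSH replicate 3 were among the 292.

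**Figure D1:**
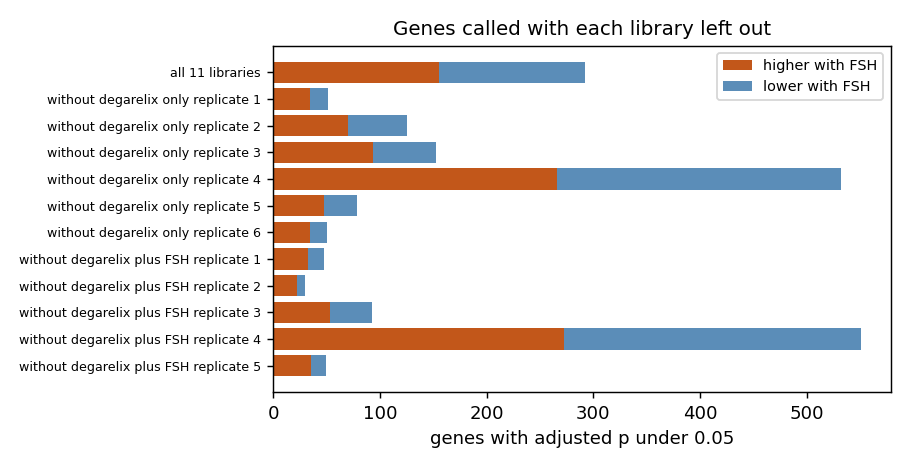
Number of genes with an adjusted p under 0.05 (x axis) with all 11 libraries and with each library left out in turn (y axis), split into genes higher and lower with FSH. The count is 292 with all libraries, 30 without FSH replicate 2 and 551 without FSH replicate 4.

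The 12 higher genes with the smallest p were Cdk2, a cell cycle kinase (19.5 ± 0.925 to 29.9 ± 1.80 CPM, adjusted p = 0.00263), Chn1, Chp2, Smtn, Cd300lg, Tcf7l1, Gpihbp1, Sox17, Mapk8ip3, Ggta1, Ajuba and Adamts7. Their log2 changes lay between 0.45 for Mapk8ip3 and 0.86 for Cd300lg, every FSH library lay above the degarelix only libraries, and all 12 kept their call with any library left out. The 12 lower genes with the smallest p were Mob3a (65.5 ± 2.86 to 47.5 ± 1.64 CPM, adjusted p = 0.00284), Tbl2, the calcineurin regulator Rcan1 (100.3 ± 8.42 to 62.5 ± 7.39 CPM, adjusted p = 0.00524), Stoml1, Sntb1, Pid1, G3bp2, Ergic1, Ywhag, Insig1, the lactate and pyruvate transporter Slc16a1 and the growth factor Pdgfc. Their log2 changes lay between -0.45 for Ywhag and -1.17 for Insig1, and every FSH library lay below the degarelix only libraries. Leaving out FSH replicate 2 ended the calls of Ergic1 and Ywhag (adjusted p = 0.0525 for both), Insig1 (0.0604), Slc16a1 (0.0622) and Pdgfc (0.0661). That of Slc16a1 also ended without FSH replicate 1 (0.0526) and that of Pdgfc without degarelix only replicate 1 (0.0502).

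Among genes past the threshold with a mean of at least 1 CPM, the largest rises included those of the tyrosine kinase Srms (log2 change 1.21 ± 0.17, adjusted p = 0.0089) and the matrix protease Adamts4 (log2 change 1.20 ± 0.23, adjusted p = 0.0311). The largest falls among them were those of LOC684841 (ENSRNOG00000053081; log2 change -1.40 ± 0.33, adjusted p = 0.0466), a symbol that stands on more than 1 gene row, Dhcr7 (-1.20 ± 0.26, adjusted p = 0.0400) and the oxytocin receptor Oxtr (117 ± 38.6 to 52.0 ± 6.62 CPM, -1.17 ± 0.22, adjusted p = 0.0311). Of these genes, only Srms kept its call with any library left out. The call of LOC684841 stood only without degarelix only replicate 4 or FSH replicate 4 (adjusted p up to 0.113 without one of the others). The call of Adamts4 ended without degarelix only replicates 1, 2, 5 or 6 or FSH replicates 2, 3 or 5 (adjusted p up to 0.0757), and that of Oxtr without degarelix only replicates 1, 5 or 6 or FSH replicates 1, 2, 3 or 5 (up to 0.0818). The call of Dhcr7 stood only without degarelix only replicate 4 (adjusted p up to 0.0982 without one of the others).

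**Figure D2:**
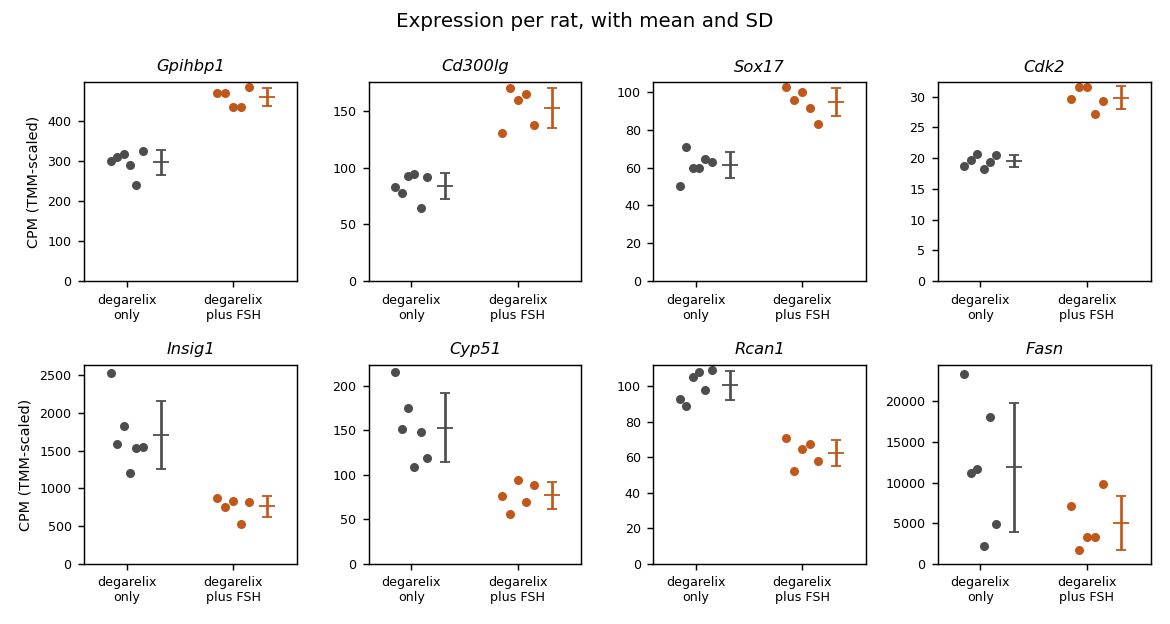
TMM-scaled CPM (y axis) of 8 genes in each rat (points) of the degarelix only (n = 6) and degarelix plus FSH (n = 5) groups, with mean and SD beside the points. The groups do not overlap for Gpihbp1, Cd300lg, Sox17, Cdk2, Insig1, Cyp51 and Rcan1, while Fasn spreads widely and overlaps.

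Cholesterol synthesis passed limma's camera test as lower with the preset correlation (adjusted p = 3.47e-07), and not with an estimated correlation of 0.377 (adjusted p = 0.736), with 4 of 19 members past the threshold over all genes. The exact permutation p of its scores was 0.0108 (0.169 adjusted over the 39 lists). Other splits of the libraries also gave this list a smaller camera adjusted p with the preset correlation. It was 9.04e-14 and 2.03e-09 in splits with 4 FSH rats in the group of 5. Splits with 3 FSH rats there gave 6.23e-09 and 5.73e-08, and a split with 1 gave 1.06e-10. The list median was -0.48 log2 units (-0.30 without degarelix only replicate 1), 17 members lay lower and 2 higher, and the mean score of the list lay below the degarelix only mean in 5 of 5 FSH libraries. Insig1, the lanosterol demethylase Cyp51 (153 ± 38.8 to 76.8 ± 15.4 CPM, log2 change -0.99 ± 0.18, adjusted p = 0.0308), the squalene synthase Fdft1 (-0.57 ± 0.12, adjusted p = 0.0396) and Dhcr7, the enzyme of the last step (188 ± 60.6 to 82.0 ± 21.6 CPM), passed the threshold over all genes. Adjusted over the list alone, 9 members passed, all lower. With 1 library left out, the call of Insig1 ended without FSH replicate 2 (adjusted p = 0.0604), that of Cyp51 without degarelix only replicates 1 or 5 or FSH replicates 1, 2 or 5 (up to 0.0738), that of Fdft1 stood only without degarelix only replicate 4 or FSH replicate 4 (up to 0.096) and that of Dhcr7 only without degarelix only replicate 4 (up to 0.0982).

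Fatty acid synthesis genes had the deepest median of the lists that passed, -0.77 log2 units, with 15 of 16 members lower and list scores below the degarelix only mean in 5 of 5 FSH libraries. The list passed camera at an adjusted p of 0.00101 (adjusted p = 0.736 with an estimated correlation), and the exact permutation p of its scores was 0.119 (0.357 adjusted over the 39 lists). Only the elongase Elovl5 passed over all genes (242 ± 47.0 to 148 ± 25.2 CPM, log2 change -0.71 ± 0.15, adjusted p = 0.0367). Its call stood only without degarelix only replicates 3 or 4 or FSH replicate 4, and its adjusted p reached 0.0905 without one of the others. Adjusted over the list alone, Elovl5 and the acetyl-CoA synthetase Acss2 (log2 change -0.78 ± 0.23) passed as lower and Acacb, the carboxylase isoform linked to control of fatty acid oxidation, passed as higher (0.48 ± 0.14). The spread between rats was wide for the most abundant members. Fasn had 11897 ± 7946 CPM without FSH and 5041 ± 3306 CPM with FSH (log2 change -1.24 ± 0.59, adjusted p = 0.244), and the acetyl-CoA carboxylase Acaca had a log2 change of -1.38 ± 0.52 (adjusted p = 0.154). Srebf1, which encodes the lipogenic SREBP, had a log2 change of -0.27 ± 0.10 (adjusted p = 0.155).

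Triglyceride synthesis, glycolysis and citric acid cycle genes also passed camera as lower, without a member past the threshold over all genes. The camera adjusted p was 0.01 for triglyceride synthesis and 0.00351 for glycolysis (adjusted p = 0.736 for both with an estimated correlation) and 0.0237 for the citric acid cycle (adjusted p = 0.918 with an estimated correlation). Triglyceride synthesis had a median of -0.24 log2 units over 14 members (-0.38 without FSH replicate 5), and 3 passed as lower adjusted over the list alone. These were the acyltransferase Gpam (61.7 ± 34.1 to 21.9 ± 4.12 CPM, log2 change -1.49 ± 0.36), the glycerol-3-phosphate dehydrogenase Gpd1 (-0.62 ± 0.17) and Dgat2, the enzyme of the final step (-0.55 ± 0.15), while Lpin1 had -0.54 ± 0.19. Glycolysis had a median of -0.27 over 15 members, with hexokinase Hk2 (-0.48 ± 0.12) passing over the list alone and Pfkl at -0.36, Pkm at -0.54 and Gpi at -0.27. The citric acid cycle had a median of -0.16 over 15 members (-0.09 without degarelix only replicate 1), none passing over the list alone, with citrate synthase Cs at -0.45, Ogdh at -0.61, Dlst at -0.24 and Idh3a at -0.23. The citric acid cycle call ended without degarelix only replicate 1 (adjusted p = 0.133) or 5 (0.110) or FSH replicate 2 (0.223).

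Of 12 marker lists tested, only that of endothelial cells passed camera, as higher (adjusted p = 0.0012; adjusted p = 0.736 with an estimated correlation), with 1 of 9 members past the threshold over all genes. All 9 lay higher, with a median log2 change of 0.31 (0.20 without FSH replicate 1), and the list score lay above the degarelix only mean in 4 of 5 FSH libraries. The member past the threshold over all genes was the angiopoietin receptor Tek (to 135 ± 19.4 CPM with FSH, log2 change 0.44 ± 0.10, adjusted p = 0.0431), and Tek, Esam (0.32 ± 0.09), the tight junction protein Cldn5 (0.59 ± 0.18) and Vwf (0.38 ± 0.13) passed adjusted over the list alone. The call of Tek stood only without degarelix only replicates 3 or 4 or FSH replicate 4 (adjusted p up to 0.106 without one of the others). Summed over the list, the markers held 1791 ± 191.3 CPM without FSH (SD, n = 6) and 2239 ± 429.5 CPM with FSH (SD, n = 5; unadjusted p = 0.0325, exact permutation test). Vwf in FSH replicate 1 stood apart at 229 CPM.

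Cytosolic ribosomal protein genes passed camera as higher (adjusted p = 3.56e-06; adjusted p = 0.736 with an estimated correlation), with 1 of 17 members past the threshold over all genes. The median log2 change was 0.19, 16 members lay higher and 1 lower, and the score lay above the degarelix only mean in 5 of 5 FSH libraries. The member past the threshold was Rpl7 (442 ± 22.2 to 540.0 ± 25.7 CPM, log2 change 0.29 ± 0.06, adjusted p = 0.0382), and 10 members passed adjusted over the list alone, among them Rps4x (0.23) and Rps3 (0.21). The call of Rpl7 stood only without degarelix only replicate 4 or FSH replicate 4 (adjusted p up to 0.0983 without one of the others). The exact permutation p of the scores was 0.00216, the smallest the 462 splits can give, and 0.0844 adjusted over the 39 lists. Ribosomal protein genes have many near-identical pseudogenes, so their counts are uncertain.

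Interferon response and heat shock genes passed camera as lower (adjusted p = 0.00301 for both), and not with an estimated correlation (adjusted p = 0.918 and adjusted p = 0.736). The median of the interferon list was -0.48, with 16 of 18 members lower and 1 past the threshold over all genes. The antiviral gene Mx2 (-1.01 ± 0.42), Ddx58 (-0.56 ± 0.24) and Irf7 (-0.90 ± 0.39) passed neither over all genes nor over the list alone. The call of the list ended without degarelix only replicate 4 (adjusted p = 0.0613) or FSH replicate 4 (0.0572). All 9 heat shock members were lower (median -0.62, or -0.36 without degarelix only replicate 4), none passed over all genes, and Hspa1b, Dnajb1 (-0.62 ± 0.21) and Hsp90aa1 (-0.75 ± 0.26) passed over the list alone, while Hspd1 had -0.28 ± 0.12. Hspa1b (-3.18 ± 1.06) was high in degarelix only replicate 4, at 160.6 CPM, against 4.46 to 49.0 CPM in the other degarelix only libraries. Hsp90aa1 held 3.40 ± 1.39 CPM without FSH and 2.02 ± 0.233 CPM with FSH. That is low for a usually abundant gene, so its change is uncertain.

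**Figure D3:**
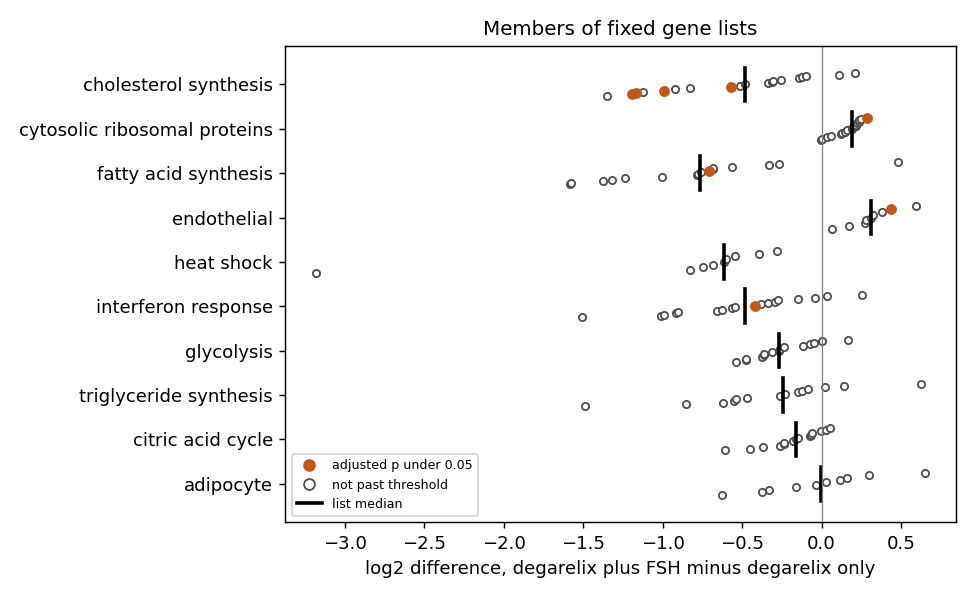
Log2 difference, degarelix plus FSH minus degarelix only (x axis), of each tested member (points) of the 9 lists past the camera threshold and of the adipocyte markers, with the list median as a bar and filled points for members with an adjusted p under 0.05 over all genes. Cholesterol synthesis lies mostly below 0 (median -0.48), endothelial markers lie above 0 (median 0.31), and the adipocyte markers straddle 0.

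In all, 9 of 39 lists tested passed camera with the preset correlation (8 of 27 gene lists, 1 higher and 7 lower, and 1 of 12 cell type marker lists, higher). None passed with an estimated correlation, where the lowest adjusted p was 0.736. Of 100 splits of the 11 libraries into 6 and 5, the real one included, 76 gave 9 or more lists past the threshold with the preset correlation.

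The other 19 gene lists tested did not pass. Insulin signalling and glucose uptake came closest (median -0.16, adjusted p = 0.0675), followed by the glucocorticoid response (median 0.30, adjusted p = 0.0926). The median log2 changes of further metabolic lists were 0.06 for lipolysis and lipid droplet, 0.04 for lipid uptake and transport, 0.04 for fatty acid oxidation, -0.06 for the respiratory chain and ATP synthase, -0.03 for brown and beige adipocyte genes, -0.15 for adipokines and -0.06 for adipogenesis regulators. They were 0.30 for the cAMP response, 0.16 for the gonadotropin and sex steroid pathway, 0.17 for angiogenesis and hypoxia, -0.08 for the circadian clock, 0.15 for immediate early genes and -0.12 for the unfolded protein response. They were -0.13 for inflammatory cytokines and chemokines, -0.04 for antigen presentation by MHC class II, 0.01 for extracellular matrix and fibrosis and -0.04 for the cell cycle. Members of these lists past the threshold over all genes were Ptpn1 (log2 change -0.49) for insulin signalling, Gpihbp1 for lipid uptake, Cpt1a (0.46) for fatty acid oxidation, and Gata2 (0.41) and Rxra (-0.72) for adipogenesis regulators. The signs of the median, the mean and the test did not agree for adipogenesis regulators, lipid uptake and transport, extracellular matrix and fibrosis, antigen presentation by MHC class II, and the T and NK cell markers. The medians of all 19 gene lists that did not pass moved by over 1.5 times or turned sign with at least 1 library left out. With 1 library left out, that of the cAMP response was 0.10 to 0.29 and that of the glucocorticoid response 0.12 to 0.54. Without FSH replicate 3 these 2 were 0.13 and 0.12, and the median turned sign for the gonadotropin and sex steroid pathway (-0.06), the cell cycle (0.04) and antigen presentation by MHC class II (0.001116). The 13 rows of mitochondrially encoded genes held 0 counts in every library.

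The FSH receptor, Fshr (ENSRNOG00000016783), had 0 counts in all 11 libraries, of 201535684 counts in all. A count of 0 allows up to 0.127 to 0.228 CPM per library, counting error only. Ppargc1a had 0 to 10 counts per library and was below the low-count filter. Ucp1, the uncoupling protein of brown fat, was also below it, with 100 counts in FSH replicate 3 (7.43 CPM), 2 in degarelix only replicate 5, 1 in FSH replicate 1 and 0 in the other 8. The adipocyte genes named in advance did not pass over all genes. Leptin (Lep) had 3382 ± 904 CPM without FSH and 2193 ± 319 CPM with FSH (log2 change -0.62 ± 0.18, adjusted p = 0.079), and Pparg, the master regulator of fat cell formation, had a log2 change of -0.38 ± 0.11 (adjusted p = 0.0893). Adiponectin (Adipoq) had 11162 ± 863 and 11379 ± 1807 CPM (log2 change 0.03 ± 0.12, adjusted p = 0.91), a difference that turned sign without degarelix only replicate 3 or FSH replicate 4. Log2 changes were -0.28 ± 0.15 for lipoprotein lipase Lpl (adjusted p = 0.281), -0.55 ± 0.15 for Dgat2 (0.0764), 0.12 ± 0.15 for Lipe (0.67), 0.16 ± 0.21 for Pnpla2 (0.68), 0.89 ± 0.46 for the estrogen receptor Esr1 (0.274) and -0.25 ± 0.27 for the chemokine Ccl2 (0.607).

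Of the cell type markers, those of adipocytes had a median log2 change of -0.003014 (adjusted p = 0.605) and summed to 47960 ± 4320 CPM without FSH and 50920 ± 5909 CPM with FSH. The medians were 0.07 for fibroblasts and adipocyte progenitors, 0.21 for lymphatic endothelium, 0.19 for smooth muscle and pericytes, 0.03 for macrophages, 0.08 for lipid-associated macrophages, 0.11 for dendritic cells, 0.04 for T and NK cells, -0.06 for mast cells and 0.73 for red blood cells, none past the threshold. Smooth muscle and pericyte markers were closest (10 of 10 members higher, adjusted p = 0.0926), and 5 of 5 red blood cell markers lay higher (adjusted p = 0.154). The medians of all 11 marker lists that did not pass moved by over 1.5 times or turned sign with at least 1 library left out. That of red blood cells was 0.16 without FSH replicate 4 and 1.20 without degarelix only replicate 1. Among dendritic cell markers, Zbtb46 passed over all genes (log2 change 0.69, adjusted p = 0.0318). Markers of 8 further sources had too few genes past the low-count filter for a test. Their summed CPM without and with FSH were 4.70 and 4.43 for B cells, 10.2 and 8.62 for neutrophils, 3.65 and 5.44 for mesothelium, 15.6 and 13.6 for skeletal muscle, 1.31 and 1.20 for kidney, 97.5 and 96.2 for adrenal, 175 and 187 for pancreas, and 17.5 and 22.5 for mammary or other epithelium. Schwann cell and nerve markers had a median log2 change of 2.12 (adjusted p = 0.189), which was 0.23 without FSH replicate 3. In that library the myelin gene Mbp reached 1314 CPM, where the other 10 libraries had a median of 66.2 CPM and a highest value of 90.9 CPM.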

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

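The test for nerve tissue was chosen after FSH replicate 3 had been seen to stand apart, and before the values of its genes were seen. It replaced a count over the markers that single out this library, which cannot serve as a test. A sample counts as standing apart where its gap to the nearest other sample of its group is above Dixon's 95% critical value for the group's range. This holds for 9 of 170 gene or marker values per group, where chance alone gives about 8.5.

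The clearest pattern is in FSH replicate 3, where the summed Schwann cell and nerve markers reached 15600 CPM against 3405 to 4762 CPM in the other FSH libraries. Of the 9 markers, 8 lay at 4 times or more the median of the other 10 libraries, among them the myelin genes Prx (32.61 times), Mbp (19.85 times) and Pmp22 (7.585 times). The exception, S100b (1.103 times), has a high baseline of 4225 CPM in the other libraries, and adipocytes also express it. In a second list of Schwann cell and myelin genes, which shares none with the first, 11 of 12 lay at 4 times or more that median, and 0 of 12 did so in each of the other libraries. These values are what a piece of myelinated nerve in this tissue sample would give, and no biological explanation was tested, since the other 4 FSH rats do not share the pattern. Without this library 92 genes passed in place of 292, and the medians of the synthesis lists and of the endothelial markers kept over 80% of their size.

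FSH replicate 3 was also the rat with the highest Ucp1 (7.426 CPM against 0 to 0.06006 CPM in the other FSH libraries). Ucp1 in degarelix only replicate 5 was 0.1238 CPM, from 2 counts, against 0 in the other libraries of its group. Hspa1b was 160.6 CPM in degarelix only replicate 4, against 4.458 to 49.03 CPM. Tcf7l1 was 67.03 CPM in degarelix only replicate 2 (others 54.64 to 58.17), Tek 118.7 CPM in degarelix only replicate 3 (others 90.29 to 100.1) and Srms 2.972 CPM in degarelix only replicate 6 (others 1.656 to 2.105). In the FSH group, Vwf was 229 CPM in replicate 1 (others 128 to 151) and Adipoq 14580 CPM in replicate 4 (others 10240 to 10880).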

How the results depend on the processing

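Thinning was the only alternative here chosen after the data were seen. The gene count moved with single libraries and with the test: leaving out each library in turn gave 30 to 551 genes (22 to 272 higher, 8 to 279 lower) against 292. It was 1103 (540 higher, 563 lower; 284 shared with the 292) with DESeq2, 635 (330 and 305; 291 shared) with quality weights, 601 (316 and 285; all 292 shared) with 1 surrogate variable, 962 (511 and 451) at an adjusted p under 0.10 and 87 (42 and 45) with the 1.5-fold limit, where the last 2 follow from the limits themselves. Other scalings, filters, plain voom, edgeR without robust estimation and thinning gave 200 to 333. With the replicate number as a replicate block it was 14 (10 and 4; 13 shared). This fit leaves out degarelix only replicate 6, and leaving out that library without a block gave 50. Adding the block, which also takes up residual degrees of freedom, moved 50 to 14. The fit with the block had 8 gene lists and 2 marker lists past camera. Deviations of same-numbered rats correlated at 0.118, -0.11, -0.109, 0.13 and 0.124, and 1 of 5 degarelix only rats correlated best with its own number, so the numbers do not pair the rats. The 9 list calls held under every scaling, filter, thinning and block setting. Camera with an estimated correlation called 0 gene lists and 0 marker lists (adjusted p = 0.736 for 7 lists, 0.918 for interferon and the citric acid cycle). Fry called 2 gene lists, ribosomal proteins and angiogenesis and hypoxia, and 0 marker lists, with adjusted p of 0.0885 for cholesterol synthesis, 0.154 for triglyceride synthesis, 0.225 for endothelial markers, 0.271 for fatty acid synthesis, glycolysis and heat shock, 0.466 for interferon and 0.472 for the citric acid cycle. With 1 library left out, 1 to 3 marker lists passed (3 without degarelix only replicate 1, 2 without FSH replicates 2 or 5), the adjusted p of the citric acid cycle ranged from 0.00144 to 0.223 and that of interferon from 7.02e-05 to 0.0613, with the other 7 past the threshold each time. Of 1606 values of 73 named genes under the alternatives, 1426 kept side and direction, 129 lost the call, 48 gained one and 3 reversed, all of Adipoq, which was never called: -0.0083682 without degarelix only replicate 3, -0.077764 without FSH replicate 4 (range 0.063448 down to that value with 1 library left out) and -0.0027693 with 1 surrogate variable. Of 36 named genes past the threshold, 20 kept the call with any library left out. Apart from the limits and numbers of libraries, the cause was not tested. Depth limits the weakest genes: Fshr and Ucp1 cannot be told from 0 below 0.127 to 0.228 CPM.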

Other observations

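The 2 tests on the share of adipocytes were written after the result was seen, the rest before, though thinning was added once the data had been seen, and the genes in the first paragraph were chosen after their values were seen. For the fasting-induced genes the rule was tightened after its first outcome, and for the markers of other cell types a condition per rat was added after its first outcome. Both had first counted against the explanation and now leave it open, because the first rules did not allow for the spread between genes or for genes of a list moving together.

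Single genes higher among the 292 were the sphingosine receptor S1pr1 (128 ± 14.5 to 185 ± 7.12 CPM, log2 change 0.53, adjusted p = 0.0098), Sox18 (0.58), nitric oxide synthase Nos3 (0.43), Eng (0.42) and Rbp7, an endothelial retinol-binding protein (371 ± 129 to 839 ± 140 CPM, log2 change 1.18, adjusted p = 0.0311), each higher in 5 of 5 FSH libraries. The incretin receptor Gipr (22.5 ± 5.42 to 45.6 ± 14.7 CPM, log2 change 1.02), the vitamin D receptor Vdr (0.91) and Cpt1a, which admits fatty acids to mitochondria (0.46), were also higher. Single genes lower among the 292 were the desaturase Fads1 (132 ± 35.0 to 67.0 ± 18.1 CPM, log2 change -0.98), the acyl-CoA synthetases Acsl3 (-0.60) and Acsl6 (-0.89), Rxra, the partner of Pparg (60.6 ± 9.59 to 36.9 ± 7.58 CPM, log2 change -0.72), Irs3 (-0.55) and the insulin receptor phosphatase Ptpn1 (-0.49). By edgeR's quasi-likelihood test their adjusted p lay between 0.0098 for S1pr1 and 0.0440 for Cpt1a. Pnpla2 (2.68 CPM without FSH), Hsp90aa1 (3.40 CPM) and Rps6 (0.635 CPM) were low for genes usually abundant in fat or in every cell.

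The gene count stands out from other splits of the libraries. Of 100 splits into 6 and 5, only 1, the real one, called as many as 292 genes, and the highest other called 156. So high a gene count was rare among the splits run, but these were 100 of 462, so chance is not excluded. The lists do not stand out even in this way: 76 of the 100 splits called 9 or more with the preset correlation, and the highest other called 18.

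The first pattern weighed is the lower expression of fatty acid and cholesterol synthesis genes, with a joint median of -0.6865 (-0.517 without degarelix only replicate 1). A smaller share of adipocytes would lower their markers alike, but these had a median of -0.003014 (SD between members 0.368). Of the 10 markers, 5 lay higher and 5 lower, and adjusted over the list alone 2 passed as higher and 2 as lower. The median therefore averages opposed changes and is only a rough gauge of the adipocyte share. Thinning every library to the smallest total count left the joint median at -0.6757. Thinning keeps each gene's expected share of the counts, so this median could hardly move. It therefore cannot show whether other differences between libraries of unlike depth play a part. Leaving out FSH replicate 3 left the joint median at -0.7033, so that library alone does not account for the pattern. Less insulin or food before harvest could lower the same genes; 8 fasting-induced genes had a median of -0.034 (bootstrap SE 0.139, 3 higher; exact permutation p of the score 0.7403), which leaves this open. An effect of FSH itself, in this tissue, where Fshr had 0 counts, or by way of another organ, stays open as an untested hypothesis, beside chance, which the splits do not exclude for the lists.

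The second pattern weighed is the higher expression of endothelial markers (median 0.31), which does not rest on FSH replicate 3 alone, without which the median was 0.3448, but fell to 0.20 without FSH replicate 1. Other markers of vessels, and those of blood, lay the same way, none past the threshold: medians were 0.19 for smooth muscle and pericytes (10 of 10 higher, 0.10 to 0.29 with 1 library left out), 0.21 for lymphatic endothelium (4 of 6, 0.12 to 0.59) and 0.73 for red blood cells (5 of 5, 0.16 without FSH replicate 4, 1.20 without degarelix only replicate 1). Members of a list moved together (estimated correlation 0.701 for endothelial markers, 0.46 for smooth muscle and pericytes, 0.924 for red blood cells). The counts of members are therefore weak support. Per rat, the smooth muscle and pericyte score lay above the degarelix only mean in 3 of 5 FSH libraries. The exact permutation p of the scores was 0.271 for smooth muscle and pericytes, 0.351 for lymphatic endothelium and 0.206 for red blood cells. A larger share of endothelial cells may account for the higher endothelial markers. In a second endothelial list, 14 of 15 genes were higher (median 0.336). The exact permutation p of its score was 0.1017, however, and Esm1 had a log2 change of -1.13. Eng and Nos3 of this list are also among the single genes named above, so they are not separate support. A smaller share of adipocytes raising every other type also stays open: markers of fibroblasts, macrophages and T cells had a median of 0.04417, yet per rat the endothelial score exceeded theirs by 0.267 between groups with an exact permutation p of 0.2576. The adipocyte markers themselves lend it no support. Their median was -0.003014, and they summed to 47960 ± 4320 CPM without FSH and 50920 ± 5909 CPM with FSH. More endothelial cells and higher expression per cell under FSH cannot be told apart in whole tissue.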
